A study of Mus musculus with 4 samples.

How the data were processed

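Bulk RNA-seq of ovalbumin-specific CD8 T cells sorted from E.G7 tumours was analysed, with 2 libraries labelled WT (floxed Smad4) and 2 labelled KO (floxed Smad4 with Cd8-cre). Per the labels' protocols, total RNA was extracted with Trizol and the libraries were made at BGI. Each library had 1 deposited table with a count and an FPKM value for each of 14082 genes. The submitters' processing notes name mm10, Trim Galore 0.4.4, Bowtie2, featureCounts, edgeR and DESeq2, with neither roles nor order. The gene annotation, the strandedness of the library and the setting of the read counting are not given in the sources used here.

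The deposited counts are whole numbers of reads per gene, per the file headers and the values, and were used as the authors made them. Each listed gene had at least 20 counts summed over the 4 libraries. The deposited FPKM values, per the file headers, were used only to learn how the tables were made and entered no test. Dividing count by FPKM gave 1 factor per library, equal to 1.01 times the summed counts in both WT libraries and 1.06 times in both KO libraries, so the FPKM values were scaled to totals other than those of the listed genes. The gene lengths they imply equalled the exon length in GENCODE M21 within 0.1% for 98.3% to 98.4% of genes with at least 50 counts. M21 is an annotation of GRCm38, the assembly called mm10. Of the listed symbols, 13906 were found in M21, and coordinates are from that annotation, counted from 1. Of 13885 genes with a single position, 99.5% were protein coding. Ecrg4 and Klrh1 were not matched, so no position is given for them.

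Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr defaults with a count minimum of 10 and a total minimum of 15, robust glmQLFit and glmQLFTest). A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05. The filter removed 724 genes and left 13358. Standard errors of log2 fold changes were taken from the fold change and its F statistic, CPM are TMM scaled, and a ± sign gives the SD over the 2 libraries of a group. Common biological variation was 9.31%. The replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 7.74 between the WT and 10.0 between the KO libraries (medians per gene 2.03 and 3.22), so neither pair was merged as 1 library listed in duplicate. Separate preparations of the same RNA would exceed counting noise too, so this does not show separate biological samples. Summed counts ranged from 24366540 to 26218277, so genes of low CPM rest on few reads and have wide errors.

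Fold changes of gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. With the correlation estimated, camera's test also has only the 2 residual degrees of freedom of the fit. The 27 lists were fixed before the data were examined, and 26 had at least 3 tested members. None of 6 sex-linked genes was listed, so that list gave no value. Some genes are in more than 1 list: Ctla4, Il2ra and Cd4. Genes were named by a rule fixed before the data were examined: Smad4, the 12 called genes with the largest change in each direction among those with a mean of at least 5 CPM and no overlap between the groups, and up to 6 or 4 members of each list, by p and then by mean CPM. Of 1181 higher and 1327 lower genes that qualified, 12 and 12 were named. Predicted or unnamed genes were not ranked (35 were called), nor were T cell receptor and immunoglobulin segments, of which 2 were tested. edgeR, DESeq2 and limma-voom called 0 of these segments, and 1 was higher at an unadjusted p under 0.05 (edgeR).

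The edgeR step was tested on simulated counts for this comparison, with 200 genes changed by known folds among 13129 tested. It recovered 60.0% of genes changed 1.5-fold, 80.0% at 2-fold, 86.0% at 3-fold and 76.0% at 4-fold, and 4.43% of its calls were false. Of genes under 5 CPM it recovered 0 of 11 changed 1.5-fold and 12 of 24 changed 4-fold, and of genes with at least 5 CPM 30 of 39 and 26 of 26. The alternatives tried were other scalings (RLE, library totals alone, upper quartile), other filters, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, an adjusted p of 0.1 and glmTreat at 1.5-fold. Leaving out mitochondrial genes and crossing the replicate numbers were added after the data were seen. Genes overlapping another tested gene, and paralogs whose reads could be split, are called uncertain where named. Some genes that the naming rule selects are not reported here.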

Results

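Ovalbumin-specific CD8 T cells were sorted by flow cytometry from subcutaneous E.G7 tumours, and their total RNA was sequenced in bulk. E.G7 is an ovalbumin-expressing derivative of the EL4 mouse T lymphoma line. The host mice carried a floxed Smad4 gene, either alone (labelled WT) or together with Cd8-cre (labelled KO), and each group had 2 libraries. Summed gene counts were 24366540 and 25790107 in the libraries labelled WT and 25806382 and 26218277 in those labelled KO. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The single comparison, KO over WT, asks how RNA of these sorted samples, which also held transcripts of other cell types, differs with the Smad4 genotype. The study's title names cytotoxic function as its subject.

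Smad4, which encodes the shared partner of receptor-activated SMAD proteins in TGF-beta and BMP signalling, was read first as a check of the labels. It lies on chromosome 18 from 73639009 to 73703780 on the minus strand of mm10 and is annotated as protein coding. Its counts were 752 and 736 in the libraries labelled WT and 779 and 1088 in those labelled KO, or 30.6 ± 1.62 and 34.8 ± 7.79 CPM (counts normalised to library size, with TMM factors; SD, n = 2 each). The log2 fold change was 0.19 with a 95% confidence interval of -0.12 to 0.49 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.397). Smad4 was therefore not lower in the libraries labelled KO, and every direction given here is between libraries labelled KO and WT. A gene-level count also includes exons that Cre does not remove, so it cannot show whether the floxed part was lost. It further includes reads of other cell types, whose transcripts were present in every library and in which Cd8-cre need not act. Without KO replicate 1 the log2 fold change became 0.40 (edgeR adjusted p = 0.00806), and without KO replicate 2 it was -0.063 (edgeR adjusted p = 0.784). Smad4 adjusted p-values lay between these under all other alternatives with no fold threshold.

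Members of the cytotoxic and effector factor lists were among the deepest falls in the libraries labelled KO. Perforin (Prf1), the pore-forming protein of cytotoxic granules, was 4.62-fold lower, at 786 ± 19.7 CPM in WT and 170 ± 4.37 CPM in KO (SD, n = 2 each). Granzyme B (Gzmb), a granule protease, was 4.42-fold lower, at 398 ± 1.29 and 90.1 ± 5.0 CPM. The T-box transcription factor Eomes was 5.34-fold lower, at 31.8 ± 2.19 and 5.94 ± 1.49 CPM. Glp1r, which encodes the glucagon-like peptide receptor, had the deepest fall under the naming rule, 13.3-fold, from 31.7 ± 0.954 to 2.36 ± 1.27 CPM. The transcription factor gene Osr2 was 8.45-fold lower and the serpin gene Serpinb9b 6.98-fold lower. Fcrl6, Slc17a6, Klrh1, Upk1a, Insrr and Unc13b made up the rest of the 12 deepest falls, with log2 fold changes from -2.47 for Fcrl6 to -2.09 for Unc13b. For the 12 falls, adjusted p-values ranged from 2.04e-10 for Prf1 to 0.000124 for Insrr (edgeR quasi-likelihood, Benjamini-Hochberg). Prf1 lies on chromosome 10 from 61297833 to 61304680, Gzmb on chromosome 14 from 56258838 to 56262260, and Eomes on chromosome 9 from 118478212 to 118486132 (mm10).

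The 12 steepest rises under the naming rule included 1 member of the neutrophil list. That gene, S100a9, which encodes a calcium-binding protein abundant in neutrophils, was 4.20-fold higher, at 112 ± 2.71 CPM in WT and 472 ± 0.985 CPM in KO (SD, n = 2 each). Il1f9, an interleukin-1 family cytokine, was 5.95-fold higher, at 19.3 ± 0.956 and 115 ± 12.2 CPM. Ecrg4 rose 11.5-fold, from 2.99 ± 0.410 to 34.5 ± 0.459 CPM, and the apolipoprotein L gene Apol7c rose 11.3-fold, from 2.42 ± 0.0247 to 27.4 ± 4.33 CPM. Clusterin (Clu, 4.37-fold), the chitinase-like gene Chil1 (4.32-fold), Steap4 (5.34-fold), Sema6d (5.26-fold), Asprv1 (4.35-fold) and the ectonucleotidase gene Entpd3 (4.31-fold) also rose. The values of Cryab (6.18-fold), which overlaps Hspb2 on the opposite strand, and of the stefin gene Stfa2l1 (4.29-fold), which has near-identical paralogs, are uncertain. For the 12 rises, adjusted p-values ranged from 2.04e-10 for S100a9 to 0.000180 for Stfa2l1 (edgeR quasi-likelihood, Benjamini-Hochberg). S100a9 lies on chromosome 3 from 90692632 to 90695721 and Il1f9 on chromosome 2 from 24186476 to 24193568 (mm10).

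Across 13358 tested genes, 1354 were higher and 1472 lower in the libraries labelled KO, 21.2% of the total. Of these, 268 were higher and 288 lower by more than 2-fold. Higher calls made up 47.9% of all calls, but 67.5% with library totals alone as the scaling (2105 higher and 1013 lower). Leaving out WT replicate 1 gave 714 higher and 831 lower, and leaving out WT replicate 2 gave 837 and 922.

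**Figure D1:**
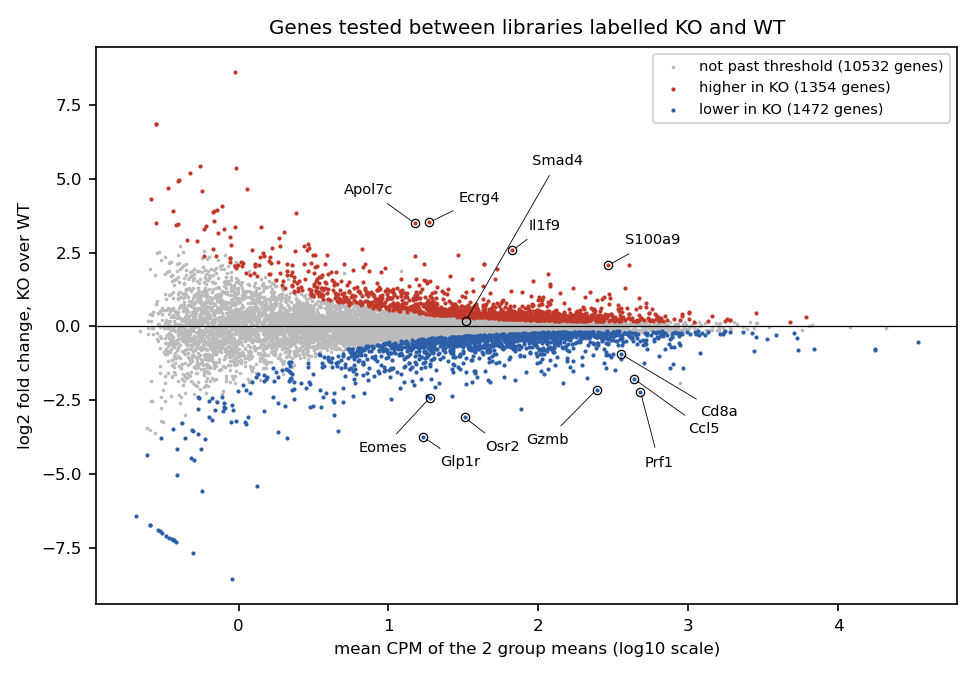
Log2 fold change, KO over WT, against mean CPM (log10 scale) for the 13358 tested genes, with 1 point per gene. Red points are the 1354 genes higher and blue points the 1472 genes lower in the libraries labelled KO, and circled genes carry their names, among them Prf1 at -2.21 and S100a9 at 2.07.

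Cytotoxic genes fell as a group, the list that the study's title concerns. Of 21 tested members, 16 were lower, 0 were higher and 5 did not pass, with 17 lower and 0 higher when adjusted over the list alone. The count of higher members was also 0 at an unadjusted p under 0.05 and 0 with DESeq2 and limma-voom, while library totals alone as the scaling gave 15 lower and 1 higher. Beside Prf1 and Gzmb, the lectin-like receptor genes Klrd1 (3.34-fold, 325 ± 12.3 to 97.5 ± 1.62 CPM) and Klrk1 (2.60-fold, 235 ± 11.7 to 90.3 ± 2.53 CPM) were lower. The granule protein gene Nkg7 was 2.68-fold lower, and Serpinb9, which encodes an inhibitor of granzyme B, was 1.96-fold lower (374 ± 12.6 to 191 ± 2.15 CPM). Their adjusted p-values lay between 2.04e-10 for Prf1 and 1.02e-07 for Serpinb9 (edgeR quasi-likelihood, Benjamini-Hochberg), each with both KO libraries below both WT libraries. The list's median log2 fold change was -1.38 (camera adjusted p = 4.37e-51 over 26 lists, adjusted p = 0.0858 with an estimated correlation). In the same libraries Cd8a and Cd8b1 were lower by 0.93 and 0.96 on the log2 scale, neutrophil markers were higher, with a list median of 1.70, and mitochondrial transcripts took 6.78% of counts against 10.3% in WT.

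**Figure D2:**
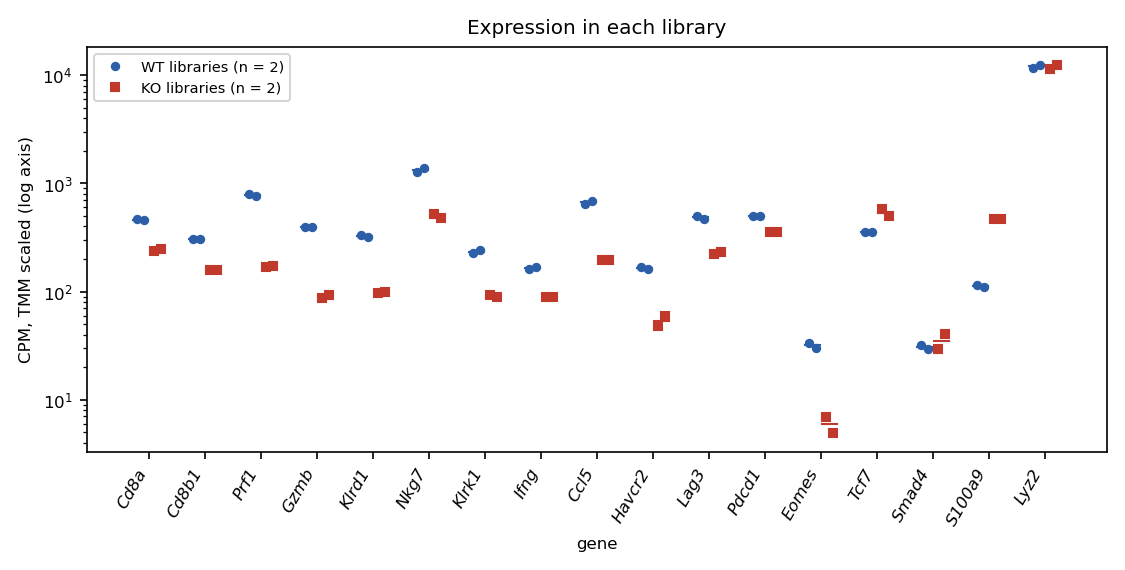
CPM on a log axis for 17 genes in each library, with circles for the 2 WT libraries, squares for the 2 KO libraries and horizontal bars for group means. Prf1 averages 786 CPM in WT and 170 CPM in KO, whereas Smad4 averages 30.6 and 34.8 CPM.

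Effector cytokine and chemokine genes moved in both directions. Of 15 tested members, 3 were higher and 6 lower, with the same counts, 3 and 6, when adjusted over the list alone. Ccl5, a T cell chemokine, fell 3.41-fold (670 ± 30.1 to 196 ± 0.857 CPM), and Ifng, which encodes interferon gamma, fell 1.84-fold (165 ± 5.49 to 89.4 ± 0.0963 CPM). Ccl4 fell 1.71-fold and Spp1, which encodes osteopontin, 1.27-fold, while Ccl1 rose 2.97-fold (log2 fold change 1.57). Adjusted p-values of these 5 ran from 7.32e-10 for Ccl5 to 0.000788 for Spp1 (edgeR quasi-likelihood, Benjamini-Hochberg). Ccl9 was 1.15-fold lower, a call lost when WT replicate 1, WT replicate 2 or KO replicate 1 was left out and with library totals alone (edgeR adjusted p = 0.0691, 0.0693, 0.112 and 0.112, against 0.0133 with all libraries and TMM). Its lowest adjusted p over the alternatives was 6.06e-05. The list's median log2 fold change was -0.10 (camera adjusted p = 0.00259, adjusted p = 0.282 with an estimated correlation). That median turned to 0.0048 without KO replicate 1 and was -0.21 without KO replicate 2, -0.04 without WT replicate 1 and -0.01 with library totals alone, while camera's direction stayed downward. Without WT replicate 1 or 2, 1 member was higher instead of 3. Cd8a, Cd8b1 and the mitochondrial share fell and neutrophil markers rose in the same libraries.

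Inhibitory receptors and exhaustion-associated factors were mostly lower in the libraries labelled KO. Of 21 tested members, 13 were lower, 1 was higher and 7 did not pass, with 13 lower and 2 higher when adjusted over the list alone. Havcr2, which encodes the inhibitory receptor TIM-3, fell 3.06-fold (164 ± 4.63 to 53.5 ± 8.15 CPM), Ctla4 2.44-fold (275 ± 8.05 to 113 ± 6.72 CPM), Lag3 2.15-fold (488 ± 20.7 to 227 ± 6.53 CPM) and Tigit 2.06-fold. The nuclear receptor gene Nr4a2 fell 2.65-fold and Rgs16, a regulator of G protein signalling, 2.38-fold. Adjusted p-values of the 6 lay between 4.42e-09 for Nr4a2 and 8.86e-08 for Havcr2 (edgeR quasi-likelihood, Benjamini-Hochberg). Its median was -0.32 (camera adjusted p = 1.73e-22, adjusted p = 0.0858 with an estimated correlation). Costimulatory and activation markers fell too, with 10 of 18 lower and 2 higher, and 12 lower and 2 higher when adjusted over the list alone. Among them Il2rb, a receptor chain for interleukins that sustain T cells, fell 2.39-fold, Tnfrsf9 2.34-fold, Cd27 2.28-fold and Icos 2.0-fold. That list's median was -0.41 (camera adjusted p = 1.75e-13, adjusted p = 0.0858 with an estimated correlation). These falls, too, came with the lower Cd8a, Cd8b1 and mitochondrial share and the higher neutrophil markers.

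Genes of effector differentiation were lower, whereas genes of stem-like and memory T cells moved both ways. Of 17 tested effector factors, 11 were lower and 1 higher, with 12 lower and 1 higher when adjusted over the list alone. Besides Eomes, the fractalkine receptor gene Cx3cr1 fell 2.34-fold (73.4 ± 1.00 to 31.4 ± 2.89 CPM), Bhlhe40 1.88-fold, Stat4 1.69-fold, Id2 1.62-fold and Irf8 1.52-fold. Adjusted p-values of the 6 lay between 8.89e-08 for Bhlhe40 and 0.000159 for Stat4 (edgeR quasi-likelihood, Benjamini-Hochberg). Effector factors had a median of -0.60 (camera adjusted p = 4.03e-11, adjusted p = 0.102 with an estimated correlation). Of 18 tested stem-like and memory factors, 5 were higher and 3 lower, with 5 and 3 when adjusted over the list alone, and 3 or 2 were higher without WT replicate 1 or 2. Bach2, a transcriptional repressor, fell 3.95-fold (23.7 ± 0.149 to 6.01 ± 0.518 CPM) and the lymph node homing receptor gene Ccr7 fell 1.47-fold. Tcf7, which encodes the transcription factor TCF-1, rose 1.51-fold (356 ± 2.72 to 538 ± 58.0 CPM). Adjusted p-values of these 3 lay between 2.26e-06 for Bach2 and 4.91e-05 for Tcf7 (edgeR quasi-likelihood, Benjamini-Hochberg). Id3 was 1.36-fold and Lef1 1.46-fold higher, but Id3 lost its call without WT replicate 2 (edgeR adjusted p = 0.0571) and Lef1 without WT replicate 1 or 2 (edgeR adjusted p = 0.110 and 0.163). Over the alternatives with no fold threshold, adjusted p-values (edgeR, DESeq2 or limma) ran from 0.000277 to 0.0571 for Id3 and from 0.0112 to 0.163 for Lef1. The stem-like list's median was 0.12, or 0.07 without KO replicate 2 and 0.20 with library totals alone, and the list did not pass against other genes (camera adjusted p = 0.361). The lower Cd8a, Cd8b1 and mitochondrial share and the higher neutrophil markers stood beside these changes as well.

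T cell receptor and co-receptor genes fell, including both chains of CD8, the co-receptor of the sorted cells. Cd8b1 was 1.94-fold lower (305 ± 1.56 to 157 ± 0.470 CPM) and Cd8a 1.90-fold lower (463 ± 11.8 to 243 ± 5.83 CPM). Prkcq, a kinase downstream of the receptor, fell 2.84-fold, Nfatc1 2.24-fold, Cd6 2.03-fold and the kinase gene Zap70 1.51-fold. Adjusted p-values of the 6 lay between 1.02e-07 for Cd8b1 and 7.21e-06 for Prkcq (edgeR quasi-likelihood, Benjamini-Hochberg). Of 28 tested members 17 were lower and 1 was higher, with 17 and 1 when adjusted over the list alone (3 higher without KO replicate 1), and the median was -0.46 (camera adjusted p = 3.46e-16, adjusted p = 0.0858 with an estimated correlation). Of the CD3 chain genes, Cd3e, Cd3g and Cd247 changed by -0.72, -0.59 and -0.90 on the log2 scale and Cd3d by -0.14. Their adjusted p-values were 1.04e-05, 2.55e-05, 8.21e-06 and 0.123 (edgeR), and these genes were chosen after their values were seen. Neutrophil markers were higher and the mitochondrial share lower in the same libraries.

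TGF-beta pathway genes moved both ways. Of 33 tested members, 4 were higher and 7 lower, with 5 and 7 when adjusted over the list alone, and 1 or 2 were higher without WT replicate 1 or 2. Library totals alone gave 7 higher and 6 lower. Itgav and Itgb8, which encode the chains of a TGF-beta-activating integrin, fell 2.22-fold (165 ± 11.6 to 74.4 ± 0.697 CPM) and 4.20-fold (8.01 ± 0.162 to 1.90 ± 0.614 CPM). Smad7, an inhibitor of the pathway and itself a target of it, fell 1.81-fold (25.1 ± 1.38 to 13.8 ± 1.55 CPM), Tgfb1 1.78-fold, Tgfbr2 1.38-fold and Tgif1 1.26-fold. Adjusted p-values of the 6 lay between 1.73e-07 for Itgav and 0.00447 for Tgfbr2 (edgeR quasi-likelihood, Benjamini-Hochberg). The 4 higher members, given here outside the naming rule, were Ldlrad4, Cdkn1a, Pmepa1 and Itgae. Their log2 fold changes were 0.68, 0.28, 1.05 and 0.82 (edgeR adjusted p = 0.00517, 0.00714, 0.0250 and 0.0298). The TGF-beta median was -0.04, or 0.05 with library totals alone, and the list did not pass against other genes (camera adjusted p = 0.332). Chemokine receptor and adhesion genes also moved both ways, with 7 higher and 9 lower of 20, and 7 and 9 when adjusted over the list alone (4 higher without WT replicate 2 or KO replicate 1). Cxcr6 fell 1.94-fold (390 ± 8.74 to 202 ± 26.7 CPM), the integrin genes Itga4 and Itgb2 fell 2.0-fold and 1.51-fold, and Ccr9 rose 1.77-fold (83.4 ± 0.160 to 148 ± 0.911 CPM). Ccr9 overlaps Slc6a20a and Itga4 overlaps Cerkl on the opposite strand, so both are uncertain. The median of that list was -0.19 (camera adjusted p = 0.244), and fry, which does not compare a list with other genes, passed it downward (limma fry adjusted p = 0.00558, the lowest over its alternatives, with a highest of 0.502). Beside both lists Cd8a, Cd8b1 and the mitochondrial share fell and neutrophil markers rose.

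Proliferation genes rose by small amounts. Of 40 tested members, 20 were higher and 1 lower, with 26 higher and 1 lower when adjusted over the list alone. The replication licensing genes Mcm2 and Cdc6 rose 1.52-fold (187 ± 10.9 to 284 ± 9.94 CPM) and 1.70-fold (36.8 ± 1.63 to 62.6 ± 0.653 CPM), and Rrm2, a subunit of ribonucleotide reductase, 1.42-fold. Cdc20 rose 1.43-fold but overlaps Elovl1 on the opposite strand and is uncertain. These 4 had adjusted p-values between 1.65e-05 for Mcm2 and 0.000241 for Cdc20 (edgeR quasi-likelihood, Benjamini-Hochberg). Proliferation genes had a median of 0.27 (camera adjusted p = 2.39e-08, adjusted p = 0.0858 with an estimated correlation). Neutrophil markers rose with them, and Cd8a, Cd8b1 and the mitochondrial share fell.

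Mitochondrially encoded transcripts took 10.3% ± 0.123 of counts in the libraries labelled WT and 6.78% ± 0.299 in those labelled KO (SD, n = 2 each). Of 13 tested mitochondrial genes 11 were lower and 0 higher, with 11 and 0 when adjusted over the list alone (0 higher at an unadjusted p under 0.05 and with DESeq2 and limma-voom). The complex I subunit genes mt-Nd2 and mt-Nd1 fell 1.78-fold and 1.72-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.78e-07 and 9.05e-07), and mt-Nd4 and mt-Nd4l, 1.69-fold and 3.47-fold, although these overlap each other and are uncertain. Mitochondrial genes had a median of -0.76 (camera adjusted p = 1.41e-19, adjusted p = 0.110 with an estimated correlation). Of 34 nuclear genes of oxidative phosphorylation 11 were higher, 0 lower and 23 did not pass, and the counts were 11 and 0 when adjusted over the list alone (1 lower at an unadjusted p under 0.05, 0 with DESeq2 and limma-voom). Ndufv1 rose 1.30-fold, Cyc1 1.29-fold (edgeR adjusted p = 0.000373 and 0.000467) and Ndufa5 1.29-fold. Ndufs1, which overlaps Eef1b2 and is uncertain, had a log2 fold change of 0.32. Ndufa5 lost its call without WT replicate 1 (edgeR adjusted p = 0.0522, the highest over alternatives with no fold threshold, of which the lowest was 0.000851). That list's median was 0.12 (camera adjusted p = 0.00308, adjusted p = 0.413 with an estimated correlation), and fry did not pass it (limma fry adjusted p = 0.0556). Without WT replicate 1 the median was 0.07, with 3 higher instead of 11. Library totals alone gave 20 higher and 0 lower (edgeR), and crossed replicate numbers 16 higher and 1 lower. Of 22 glycolysis genes 6 were higher and 0 lower, with 6 and 0 when adjusted over the list alone (0 lower at an unadjusted p under 0.05 and with DESeq2 and limma-voom), led by Pfkfb3 at 1.43-fold (edgeR adjusted p = 0.000323). The glycolysis median was 0.10 (camera adjusted p = 0.0313, adjusted p = 0.294 with an estimated correlation), and its call was lost without KO replicate 2 or WT replicate 2 (camera adjusted p = 0.120 and 0.0512) and with fry (limma fry adjusted p = 0.0544). Over all its alternatives the adjusted p ranged from 0.00481 to 0.294, and 2 members were higher without WT replicate 1, 3 without WT replicate 2, 3 with 1 lower without KO replicate 2, and 11 with library totals alone. In the same libraries Cd8a and Cd8b1 were lower by 0.93 and 0.96 on the log2 scale and neutrophil markers were higher, with a list median of 1.70.

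Interferon-response genes fell. Of 37 tested members, 21 were lower and 1 higher, with 24 lower and 1 higher when adjusted over the list alone. Cxcl9, an interferon-induced chemokine, fell 3.28-fold (59.8 ± 7.20 to 18.2 ± 3.40 CPM), and the guanylate-binding protein genes Gbp3 and Gbp7 fell 1.91-fold and 1.58-fold. Cxcl10 fell 1.62-fold but overlaps Art3 on the opposite strand and is uncertain. Adjusted p-values lay between 1.90e-06 for Cxcl9 and 9.74e-05 for Gbp7 (edgeR quasi-likelihood, Benjamini-Hochberg). Interferon genes had a median of -0.46 (camera adjusted p = 4.08e-09, adjusted p = 0.0858 with an estimated correlation). With these falls came lower Cd8a, Cd8b1 and mitochondrial share and higher neutrophil markers.

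Transcripts of other cell types were present in every library despite the sort, and their lists did not move together. Lyz2, a lysozyme of macrophages and neutrophils, took 1.15% and 1.20% of counts in the libraries labelled WT and 1.19% and 1.27% in those labelled KO. Lyz2, Ctsb, Cd74 and H2-Ab1 were among the most abundant genes in these libraries. The macrophage marker Apoe stood at 2387 and 3276 CPM in WT and KO, against 463 and 243 CPM for Cd8a. Some members of the T cell and interferon lists, such as Spp1 and Cx3cr1, are also expressed by macrophages. The source of their reads was not tested. Of 18 macrophage and monocyte markers 3 were higher and 3 lower, with 4 and 5 when adjusted over the list alone, around a median of -0.03, or 0.05 with library totals alone (camera adjusted p = 0.960). Library totals alone gave 6 higher and 1 lower, and leaving out WT replicate 1 gave 1 and 1. Apoe rose 1.37-fold and Fcgr1 fell 1.40-fold (edgeR adjusted p = 5.67e-05 and 0.000413). Of 10 neutrophil markers 6 were higher and 0 lower, with 8 and 0 when adjusted over the list alone (0 lower at an unadjusted p under 0.05 and with DESeq2 and limma-voom), around a median of 1.70 (camera adjusted p = 9.97e-29, adjusted p = 0.0858 with an estimated correlation). A replicate block gave 8 higher and 1 lower, crossed numbers 8 and 1, and leaving out KO replicate 1 gave 7 and 1. S100a8 rose 4.20-fold (154 ± 6.66 to 644 ± 4.36 CPM), the growth factor receptor gene Csf3r 2.46-fold (98.4 ± 0.900 to 242 ± 6.85 CPM) and the chemokine receptor gene Cxcr2 3.03-fold (17.8 ± 0.790 to 54.0 ± 4.5 CPM). Their adjusted p-values ranged from 2.04e-10 for S100a8 to 6.28e-07 for Cxcr2 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 10 dendritic cell and MHC class II markers 2 were higher and 2 lower, with 2 and 2 when adjusted over the list alone, and the list did not pass (median 0.05, camera adjusted p = 0.0511). It passed without KO replicate 1 or WT replicate 2 and with library totals alone (camera adjusted p = 0.0292, 0.0281 and 0.0248, the lowest over its alternatives, with a highest of 0.294). RLE factors, upper quartile factors and no filter also passed it (camera adjusted p = 0.0497, 0.0479 and 0.0467), as did fry (limma fry adjusted p = 0.0463), so this list lay at the threshold. Its median turned to -0.01 without WT replicate 1 and without KO replicate 2, and 1 member was lower when either KO library was left out and 0 (edgeR) when either WT library was left out or with library totals alone. Siglech, a receptor of plasmacytoid dendritic cells, rose 2.59-fold (66.0 ± 1.54 to 171 ± 4.34 CPM), and Flt3 rose 1.51-fold (edgeR adjusted p = 2.04e-08 and 0.00161). Cd8a, Cd8b1 and the mitochondrial share were lower in the same libraries.

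**Figure D3:**
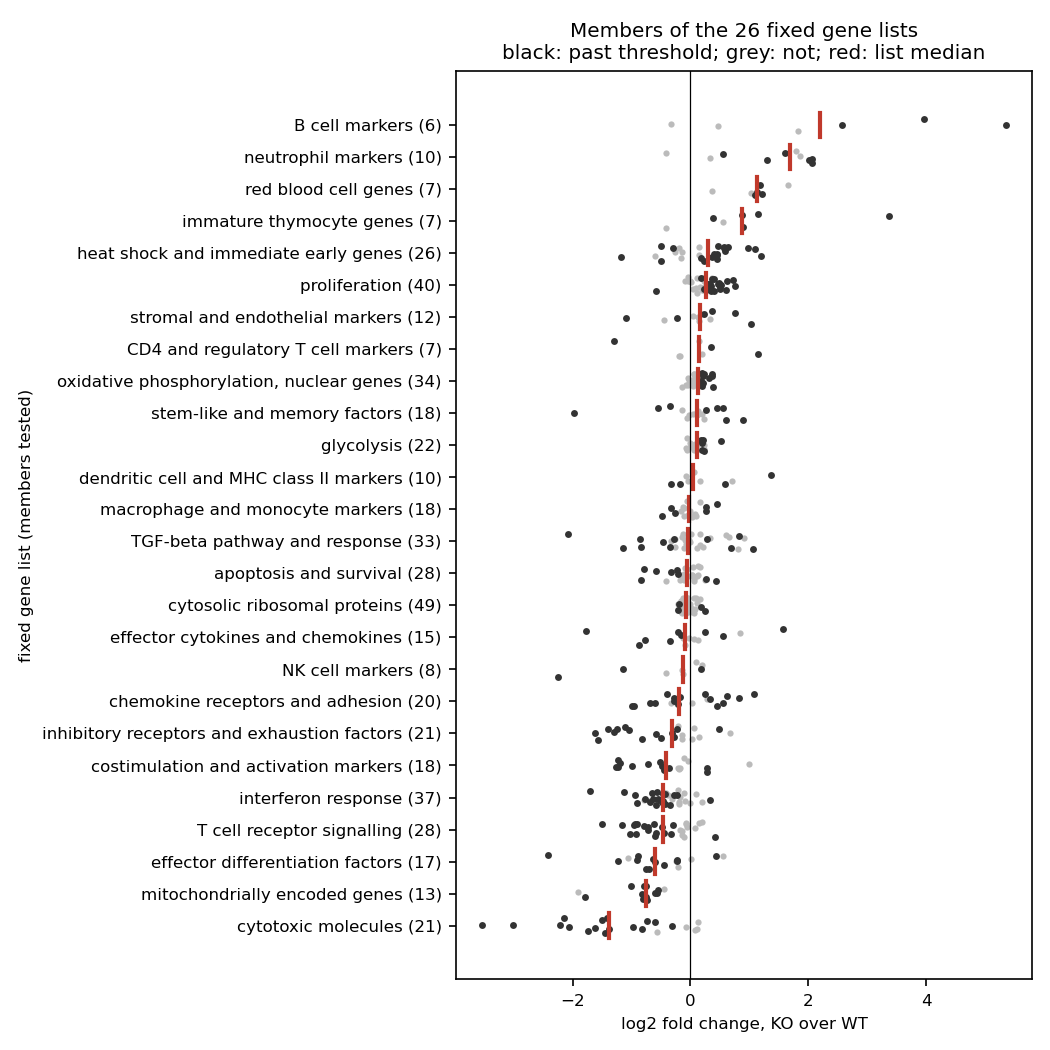
Log2 fold change, KO over WT, of each tested member of the 26 fixed gene lists, with black points past the threshold, grey points not past it and red bars at list medians. The cytotoxic list lies lowest with a median of -1.38, and the neutrophil list has a median of 1.70.

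B cell transcripts were scarce but higher in the libraries labelled KO. Of 6 tested markers 3 were higher and 0 lower, with 4 and 0 when adjusted over the list alone (0 lower at an unadjusted p under 0.05 and with DESeq2 and limma-voom), around a median of 2.20 (camera adjusted p = 0.00428, adjusted p = 0.279 with an estimated correlation). Cd79a rose from 0.683 ± 0.287 to 4.07 ± 0.201 CPM (edgeR adjusted p = 0.000984). Cd79b was the only marker of the list with at least 5 CPM in 2 libraries, and it did not pass (5.73 ± 0.0131 to 7.92 ± 0.927 CPM, log2 fold change 0.47, edgeR adjusted p = 0.156). Natural killer cell markers did not pass as a list, with 1 higher and 2 lower of 8, and 1 and 2 when adjusted over the list alone (median -0.13, camera adjusted p = 0.150). That median moved with single libraries, to 0.16 without WT replicate 2, -0.42 without WT replicate 1 and -0.61 without KO replicate 2, and the 1 higher member lost its call without any 1 of the 4 libraries. Among them Klri2 and Klra3, which is uncertain because it has near-identical paralogs, fell 2.22-fold and 4.75-fold (edgeR adjusted p = 3.28e-05 and 0.000125). Neutrophil markers were higher, and Cd8a, Cd8b1 and the mitochondrial share lower, beside both lists.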

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

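Leaving out mitochondrial genes and crossing the replicate numbers were chosen only after the results were seen. No called gene among those the naming rule selects and no list called by camera changed direction of its test under the alternatives run, but the median of the effector cytokine list turned from -0.10 to 0.0048 without KO replicate 1. Prf1, Gzmb and Eomes kept their calls. Among genes named in the text, Ccl9, Id3, Lef1, Ndufa5 and Blk lost calls with a library left out. Counts of 1 or 2 members called higher in the inhibitory receptor, costimulatory and effector factor lists, and lower in the stromal list, moved by 1 with single libraries left out. Library totals alone, meaning the summed counts of the tested genes, gave 2105 genes higher, since they omit the TMM factors. The totals behind the FPKM values were 1.06 times the summed counts in both KO libraries and 1.01 times in both WT libraries. Scaling to those totals was not tried. The 1.5-fold threshold of glmTreat left 148 higher and 211 lower by its construction. Leaving out a library gave 714 to 1605 genes higher, 831 to 1787 lower and a Smad4 log2 fold change of -0.063 to 0.40, the last past the threshold without KO replicate 1 (the cause was not tested); the lone library of a group was then assumed to vary like the others. With an estimated correlation, camera passed 0 lists (11 at an unadjusted p under 0.05), with the cytotoxic list at an adjusted p of 0.0858. For that list the estimate was 0.0038, below the preset 0.01, so member correlation does not explain its lost call. The estimate lay below 0.01 for some lists, such as neutrophil markers (-0.10), and above it for others, such as mitochondrial genes (0.32). Fry passed 16 lists, of which 13 were among the 16 that camera passed at the preset correlation. Glycolysis, nuclear oxidative phosphorylation and red blood cell genes lost their calls with fry (limma fry adjusted p = 0.0544, 0.0556 and 0.169), and the chemokine receptor, apoptosis and dendritic lists gained them (0.00558, 0.0207 and 0.0463). The labels do not pair same-numbered libraries, and the deviations of WT and KO replicate 1 correlated at -0.10 over 10040 genes. A replicate block gave 1393 genes higher and 1522 lower, with a Smad4 log2 fold change of 0.17, and the crossed numbers gave 1673 and 1770. DESeq2 gave 1163 and 1274, and limma-voom 1304 and 1467. Leaving out mitochondrial genes gave 1375 and 1458. In simulated counts 12 of 24 genes under 5 CPM changed 4-fold were recovered, against 26 of 26 with more, and 0 of 11 against 30 of 39 at 1.5-fold, so changes of low genes can be missed at this depth.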

Other observations

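Tests of scaling to Cd8a and Cd8b1, of the spread of cytotoxic fold changes, of library totals and of neutrophil against macrophage markers were chosen only after the results were seen. Heat shock and immediate early genes mostly rose in the libraries labelled KO. Of 26 tested members 15 were higher and 4 lower, with 17 and 7 when adjusted over the list alone, around a median log2 fold change of 0.30 (camera adjusted p = 9.24e-06, adjusted p = 0.102 with an estimated correlation). The rising members with the lowest p were chaperones: Hspa1a 2.13-fold (188 ± 11.9 to 402 ± 18.1 CPM) and Dnajb1 1.97-fold (315 ± 27.4 to 619.6 ± 29.4 CPM), with SD over 2 libraries and edgeR adjusted p = 1.02e-07 and 4.94e-07. Dusp2, a phosphatase induced by T cell activation, fell 2.27-fold (235 ± 21.3 to 104 ± 10.7 CPM). Hspa1a has a near-identical paralog and Hspd1 (1.51-fold higher) overlaps Hspe1, so both are uncertain. In the same libraries Cd8a and Cd8b1 were lower by 0.93 and 0.96 on the log2 scale, neutrophil markers were higher with a list median of 1.70, and mitochondrial transcripts took 6.78% of counts against 10.3% in WT. Of 28 apoptosis and survival genes 2 were higher and 6 lower, with 2 and 6 when adjusted over the list alone and 0 and 3 (edgeR) without WT replicate 1 (median -0.05, or 0.04 with library totals alone, camera adjusted p = 0.0960), and fry passed that list downward (limma fry adjusted p = 0.0207, the lowest over its alternatives, with a highest of 0.294). Cytosolic ribosomal protein genes had 2 higher and 2 lower of 49, and 1 and 1 when adjusted over the list alone (median -0.08, or 0.01 with library totals alone, camera adjusted p = 0.244, adjusted p = 0.854 with an estimated correlation). At the preset correlation that list passed without KO replicate 2 or WT replicate 2 (camera adjusted p = 0.00935 and 0.00684), with 14 and 7 lower, while the correlation estimated with all libraries was 0.744. Crossed numbers gave 4 higher and 18 lower, library totals alone 4 and 0, and leaving out KO replicate 1 or WT replicate 1 gave 0 lower (edgeR; 12 lower at an unadjusted p under 0.05, 4 with DESeq2 and 3 with limma-voom when all libraries were kept).

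Genes of immature thymocytes were higher in the libraries labelled KO. Of 7 tested members 5 were higher and 0 lower (0 lower at an unadjusted p under 0.05, with DESeq2 and with limma-voom), with 5 and 0 when adjusted over the list alone, around a median of 0.87 (camera adjusted p = 1.23e-05, adjusted p = 0.110 with an estimated correlation). Cd4 rose 2.21-fold (29.6 ± 3.73 to 65.4 ± 3.25 CPM), Arpp21 1.86-fold and Cd24a 1.82-fold. Ptcra, also in this list (log2 fold change 3.37), is taken up below among genes expressed by plasmacytoid dendritic cells. The rise of this list and that observation are therefore not separate. CD4 and regulatory T cell markers, a list that also holds Cd4 and Ctla4, had 2 higher and 1 lower of 7, and 2 and 2 when adjusted over the list alone, with a median of 0.14, a mean of 0.02 and a downward camera test (adjusted p = 0.682). Without WT replicate 2 the median of that list was -0.10. Of 7 red blood cell genes 4 were higher and 0 lower (0 lower at an unadjusted p under 0.05, with DESeq2 and with limma-voom), with 5 and 0 when adjusted over the list alone, and a median of 1.13 (camera adjusted p = 0.00308, adjusted p = 0.435 with an estimated correlation). Fry did not pass the red blood cell list (limma fry adjusted p = 0.169), and without WT replicate 1 it had 2 higher instead of 4. The globin genes Hba-a1 and Hbb-bs, which are uncertain because reads can be shared with near-identical copies, were 2.31-fold and 2.26-fold higher. Stromal and endothelial markers had 4 higher and 2 lower of 12, with 5 and 2 when adjusted over the list alone, and a median of 0.17, or 0.10 without WT replicate 2 and 0.25 with library totals alone (camera adjusted p = 0.0511), with Acta2 1.69-fold higher. The stromal list lay at the threshold: it passed without KO replicate 1 or WT replicate 1 (camera adjusted p = 0.0177 and 0.0225), with RLE factors, library totals alone, upper quartile factors or no filter (0.0497, 0.0341, 0.0479 and 0.0467), at a CPM of at least 5 in 2 libraries or as a member mean (0.0313 and 0.0190), and with crossed replicate numbers (0.0399). It did not pass without WT replicate 2 or KO replicate 2, with the replicate block, with mitochondrial genes left out, with fry (limma fry adjusted p = 0.0782) or with an estimated correlation (camera adjusted p = 0.294, the highest over its alternatives). Lower Cd8a, Cd8b1 and mitochondrial share and higher neutrophil markers stood beside all these lists.

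Lower cytotoxic transcripts came with lower Cd8a and Cd8b1, so a smaller share of CD8 T cells may lie behind part of the fall. With libraries scaled to Cd8a plus Cd8b1 reads, which moved the median of all genes by 0.94, the 21 tested members had a median of -0.44 (limma fry, Benjamini-Hochberg adjusted p = 0.0277 over 5 fry tests), with 11 lower, 5 higher and 5 neither, which argues against that share as the whole cause for the list. Library totals alone as the scaling moved the median of all genes to 0.08 and left the list median at -1.29 (limma fry adjusted p = 0.00167). The TMM factors therefore account for little of the fall. This scaling shifts all genes by a near-equal amount, so it bears on no other cause. Loss of a single cytotoxic population while another source keeps supplying Cd8a and Cd8b1 reads stays open: the fold changes of the 16 called members varied beyond their errors (chi-square per degree of freedom 66.1), but which members are confined to such a population is not known from these tables. The Smad4 genotype also stays open and was not tested. It cannot be told apart from the changes in CD8 and neutrophil markers, which separate the same 2 groups of libraries.

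Higher neutrophil transcripts were also seen in the libraries labelled KO. A smaller CD8 T cell share would raise all other cell types alike, but the neutrophil median exceeded the macrophage median by 1.73 (two-sided permutation test over 28 genes, p = 0.0002), which argues against that share as the whole cause. The permutation takes genes as its units, so its p does not measure the spread between libraries. Both medians were known when the test was chosen, so its p adds no support beyond the difference itself. More neutrophil RNA in the libraries labelled KO is a candidate source: 18 further neutrophil genes, in no fixed list, were chosen before their values were looked at, and the 17 tested had a median of 0.80 (limma fry adjusted p = 0.00446), with 12 higher, 2 lower and 3 neither. Abundant neutrophil genes S100a8 and S100a9 reached 644 and 472 CPM, and a sort for ovalbumin-specific CD8 T cells should remove such cells. Some of these genes are also expressed by monocytes and macrophages, so an inflammatory state of those cells, or a genotype effect on the tumour, stays open and was not tested.

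Siglech, Ly6d, Ccr9 and Ptcra, singled out after their values were seen, were higher together (log2 fold changes 1.37, 1.96, 0.83 and 3.37), and all are expressed by plasmacytoid dendritic cells, although Ccr9 overlaps Slc6a20a and is uncertain. More RNA of such cells is a candidate source, although the sort should remove them. Among 14 further genes of these cells, listed before their values were looked at, 6 were higher and 3 lower with a median of 0.30 (limma fry adjusted p = 0.0380). This leaves it undecided, because that median lay between the bounds set beforehand for and against such a source. Ptcra also belongs to the immature thymocyte list, which rose (median 0.87, camera adjusted p = 1.23e-05, adjusted p = 0.110 with an estimated correlation). Immature thymocytes as a source of these genes were not tested against plasmacytoid dendritic cells, so neither source is preferred here. Other sources, among them the T lymphoma cells of the E.G7 tumours, were not tested either. The genotype stays open too.

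Il17f and Blk, also singled out after their values were seen, were higher in the libraries labelled KO. Il17f had 86 and 98 counts in WT and 435 and 370 in KO, and Blk had 1 and 3 in WT and 46 and 26 in KO. Blk lost its call without WT replicate 1 (edgeR adjusted p = 0.0856). Of 12 genes listed for IL-17-producing lymphocytes 7 were tested, of which 1 was higher and 1 lower, with a median of 0.13 (limma fry adjusted p = 0.26).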
